A study of Mus musculus with 8 samples.

How the data were processed

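The data were 8 arrays, 1 per sample, of total RNA from the myocardium of male mice, 3 labelled NPRA-/- and 5 labelled NPRA+/+. RNA was amplified and labelled with Cy3 per the labels' protocols. The authors' scanner files hold linear intensity values per spot, written by Agilent Feature Extraction 11.0.1.1 per the file headers and the submitters' processing notes. The processed intensity of a spot is background-subtracted within its array, per the file headers, and not scaled between arrays. The same files hold flags of 0 or 1 for spots that are well above background, saturated or not uniform. The deposited series table holds log2 values. Their scale and normalization are not given in the sources used here. Set against the scanner values, each column ranked the probes as its own array did (rank correlation of at least 0.999), and every column had a median of 7.05, as quantile-normalized log2 intensities would. Of its 39485 entries, 39429 were matched to a probe and 56 were not used.

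Control spots were left out, spots with an outlier flag were set to missing, and log2 values of the spots of 1 probe were averaged. Each array's 75th percentile of the processed signal was subtracted on the log2 scale. A probe was well above background on an array where at least a share of 0.5 of its spots was, and probes so on at least 3 of the 8 arrays were tested (35329, with 4100 not kept). No spot was saturated (0). Probes were named through their RefSeq transcript and the RefSeq gene table of the assembly GRCm38.p6. Of 39429 probes, 27234 matched 1 symbol and 12195 none, and those tested covered 19056 symbols. The array design names another build, so no coordinates are given. Where a gene had several probes, the 1 with the highest mean stood for it, and other probes are given where they differ.

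The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all probes tested, threshold 0.05), with genotype as the only term. Every adjusted p of a probe comes from limma. Gene lists, 35 of them (20 of function and 15 of cell types), were tested with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over all lists with at least 5 measured members. A missing value in the list tests was replaced by the probe's mean over the arrays. The lists, the tests of the comparison, the rule for named genes and all but 5 of the alternatives were fixed before the data were examined. The rule for named genes took Npr1, the 12 genes of largest change in each direction among calls without overlap between the genotypes, further genes by p up to 10 where fewer passed, the 4 members with the smallest p of lists past the threshold and of the natriuretic, hypertrophy and fatty acid lists, 1 member of every other function list, and up to 3 of the brightest members of cell type lists. Clone names and predicted genes were left out.

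The labels call the samples biological repetitions, numbered 1 to 3 and 1 to 5, while the source names give 3 NPRA+/+ arrays the number 1; no label ties a sample to an animal, so p-values measure the spread between these samples. Nothing in the labels says that a number is shared between genotypes. In the data, deviations of equally numbered samples from their genotype's mean correlated by 0.63, 0.28 and 0.36 across probes with the repetition numbers, and by 0.35, 0.12 and 0.30 with the source name numbers. Each NPRA-/- sample correlated best with the NPRA+/+ sample of its own repetition number. By the rule set for this check, under which each correlation has to be over 0.1, either numbering passes. The rule cannot decide whether the numbers pair the samples, since unequally numbered samples passed it too. NPRA-/- replicate 2 correlated by 0.25 with NPRA+/+ replicate 3, and NPRA-/- replicate 3 by 0.33 with NPRA+/+ replicate 2. Blocked results are given beside the unblocked ones where a call differs. Numbers 2 and 3 shared scan day 1. No pair of arrays held the same values, and correlations between arrays lay between 0.945 and 0.994.

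Alternatives were quantile normalization, scaling to the median, normexp background correction with an offset of 50, other filters on dim probes, the deposited series table, slide, scan day and replicate number as blocks, averaging of NPRA+/+ arrays that share a source name number, other variance models, array weights, other thresholds, 1 value per gene, and leaving out each array. Normexp was run on the median spot signal, as the mean signal is not among the columns used here. Another 5 alternatives, on scan day 1 alone, without scan days 3 and 4, and quantile normalization joined with a block or with scan day 1, were added after the data were seen. The analysis was tested on simulated data with 35329 probes and the same 3 and 5 arrays. Of 50 probes changed by 1, 2, 3 or 4 on the log2 scale, 32%, 74%, 92% and 100% were called, and 7 of 156 calls (4.49%) were false. When nothing was changed, 0 of the 35329 probes were called, and on 1 probe for each of 19056 genes all 3 changed lists were found. The simulated noise was independent between probes and between arrays, without slides, scan days or an offset by signal. These rates therefore need not hold for the real arrays. Files were read with version 1.17.8 of data.table, the random block used statmod 1.5.0, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.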

Results

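Gene expression was measured in the myocardium, the heart muscle, of male untreated mice. NPRA, encoded by Npr1, is the receptor for atrial and B-type natriuretic peptide that makes cyclic GMP. The arrays carried the labels NPRA-/- (3 arrays, a deletion restricted to the heart per the series title) and NPRA+/+ (5 arrays). Total RNA of each sample was labelled with 1 dye and hybridised to 1 Agilent mouse array. The series text speaks of m6A, a methylation of RNA, but is typed as expression profiling and the arrays carry an expression design, so the signals were read as transcript levels. Between 79.5% and 92.6% of the 39429 probes were well above background per array, and the 75th percentile of the signal lay between 775 and 1253. The number of arrays limits the precision. The arrays were scanned on 4 days. Arrays with the same scan date and time in the file headers were taken to share a slide, which gave 6 slides. None of the slides (0) held both genotypes, and only scan day 1 did, with replicates 2 and 3 of each. The first principal component (47.3% of the variance) set NPRA-/- replicate 1, scanned on day 3, and NPRA+/+ replicate 1, scanned on day 4, apart from the other arrays.

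**Figure D1:**
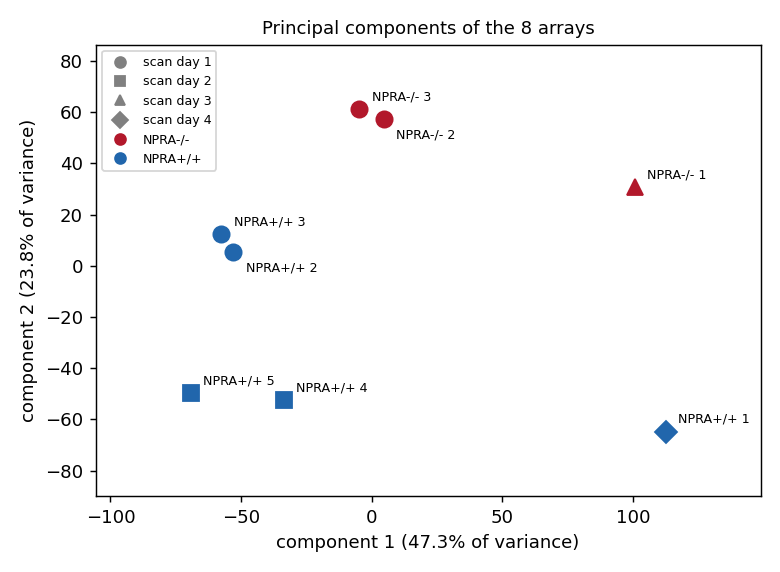
Scores of the 8 arrays on the first (47.3% of the variance) and second (23.8%) principal components of the log2 signals, coloured by genotype and shaped by scan day. Replicate 1 of either genotype lies at 100.8 (NPRA-/-) and 112.5 (NPRA+/+) on the first component, and the other arrays lie at 4.68 or below.

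Npr1, the deleted gene, was measured by 1 probe close to background. Its log2 signal relative to the 75th percentile was -6.42, -5.53 and -5.59 in NPRA-/- replicates 1 to 3, and -4.77, -6.14, -6.55, -6.00 and -5.93 in NPRA+/+ replicates 1 to 5. It was well above background on 2 of 3 NPRA-/- and 4 of 5 NPRA+/+ arrays. The means were -5.85 ± 0.50 (SD, n = 3) and -5.88 ± 0.66 (SD, n = 5), a fitted log2 fold change of 0.03 ± 0.40 (SE; limma, adjusted p = 0.978). The fitted change was -0.60 after quantile normalization (adjusted p = 0.726) and 0.78 ± 0.17 within scan day 1 (adjusted p = 0.0517). Relative to the median change of all probes Npr1 was at -0.18, and positive with normexp (0.24), within scan day 1 (0.61), without NPRA-/- replicate 1 (0.13) and without NPRA+/+ replicate 1 (0.09). The position of this probe relative to the deleted part is not given in the sources used here, so the probe does not check the labels. The genotypes below are those of the labels, and every direction rests on them.

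The comparison asked which transcripts differ in the heart when its natriuretic peptide receptor is deleted. Msln, which encodes mesothelin, a surface glycoprotein of the mesothelium that covers the heart, had the largest change among the named genes past the threshold and higher on the arrays labelled NPRA-/-. Its level was -1.42 ± 0.66 (SD, n = 3) against -3.90 ± 0.48 (SD, n = 5). Tg, the gene of the thyroid hormone precursor thyroglobulin, and Slc16a7, which encodes the monocarboxylate transporter MCT2, were lower. Tg was at -0.89 ± 0.14 against 1.23 ± 0.57, and Slc16a7 at 2.81 ± 0.54 against 4.66 ± 0.28. The median of all 35329 probes tested was itself shifted by 0.21 (log2, NPRA-/- over NPRA+/+). Changes below are relative to this shift unless called fitted, with the SE of the fit. Each limma p-value of a probe tests the fitted change against 0, not the change relative to the shift. With scaling to the median, which left a shift of -0.03, limma called 0 probes (smallest adjusted p 0.111). The shift differed by signal, from 0.63 in the dimmest of 5 equal groups of probes to 0.05 in the brightest. Set against probes of like signal, relative changes are thus too high for dim probes and too low for bright ones. With 1 probe per gene, as in the lists, the median was 0.16, so list medians near 0 take their sign from the reference.

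Relative to the shift, Msln rose by 2.27 ± 0.36 (limma, adjusted p = 0.0498, all 3 NPRA-/- arrays above all 5 NPRA+/+ arrays). Other named genes that rose were Slc16a14, a relative of the monocarboxylate transporters, by 1.36 ± 0.18, Tdpoz3 by 1.33 ± 0.18, Prss39, a serine protease gene, by 1.28 ± 0.21, and Dlx2, a homeobox transcription factor, by 1.16 ± 0.19. The odorant receptor genes Olfr1188 and Olfr259 rose by 1.34 ± 0.20 and 1.12 ± 0.18, and the vomeronasal receptor gene Vmn1r47 by 1.17 ± 0.13. Several of these were dim: Slc16a14 and Olfr1188 were well above background on 1 of 5 NPRA+/+ arrays, Dlx2 on 2 and Tdpoz3 on 4. Prss39 and Vmn1r47 were so on 2 of 3 NPRA-/- and 1 of 5 NPRA+/+ arrays. Olfr867, Clec2h, Rbm44 and Scgb2b27 were well above background on all 3 NPRA-/- arrays and on no NPRA+/+ array (0 of 5). Their fitted signals were at least 2.31-fold, 1.71-fold, 2.32-fold and 1.60-fold higher (adjusted p from 0.0453 to 0.0498), set against the lowest signal well above background or the probe's own, whichever was higher. These genes met the filter of 3 arrays only through the NPRA-/- arrays, and the bounds do not allow for the shift of dim probes. On the log2 scale the bounds of Clec2h and Scgb2b27 were 0.78 and 0.68, against a shift of 0.63 in the dimmest of 5 equal groups of probes. A second probe of Tdpoz3 had a fitted change of 0.91 ± 0.38 and did not pass. After quantile normalization the fitted change went from 2.48 to 2.26 for Msln, from 1.49 to 0.75 for Prss39 and from 1.38 to 0.68 for Vmn1r47. With the replicate number as a block, by either numbering, none of these 12 named genes passed, Msln having an adjusted p of 0.136 and 0.0838.

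Lower on the NPRA-/- arrays were Ppp1r8, a regulatory subunit of protein phosphatase 1, at -2.52 ± 0.28, Tg at -2.32 ± 0.31, Slc16a7 at -2.06 ± 0.26 and Card6, a caspase recruitment domain gene, at -1.09 ± 0.13 (limma, adjusted p = 0.0454 for Ppp1r8, 0.0498 for Slc16a7 and just under 0.05 for Tg and Card6). The remaining symbol, 3300002I08Rik, is a clone name outside the rule for named genes and was picked out after its values were seen, at -2.64 ± 0.30. All 3 NPRA-/- arrays lay below all 5 NPRA+/+ arrays for each of them. A second probe of Ppp1r8 had a fitted change of -0.10 ± 0.20. With the replicate number as a block, by either numbering, none of the 4 named genes passed, Ppp1r8 having an adjusted p of 0.136 and 0.0633. Next by p, and not past the threshold, were S100z at -2.80 ± 0.45 and Ch25h, cholesterol 25-hydroxylase, at -2.51 ± 0.42 (adjusted p = 0.0597 and 0.0637), Nhlh1 at -1.49 ± 0.23, Zfhx2 at -1.19 ± 0.17, the histone gene H3c7 at -1.03 ± 0.13 and Stxbp2 at -0.85 ± 0.11. With the replicate number as a block by source name number S100z and Ch25h passed (adjusted p = 0.0225 each), and without NPRA+/+ replicate 1 all 6 did (adjusted p from 0.0186 for H3c7 to 0.0270 for Nhlh1). Second probes of Zfhx2, Nhlh1 and Stxbp2 had fitted changes of the other sign, 0.73 ± 0.33, 0.61 ± 0.38 and 0.43 ± 0.20, none past the threshold.

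In all, 113 probes (75 gene symbols) were higher and 10 (5 symbols) lower at an adjusted p under 0.05, the smallest being 0.0453. All of these separated the genotypes without overlap, as did 5425 probes (15.4%) among all tested, against 3.57% expected by chance. That expected share takes the arrays as exchangeable, without pairs, slides or scan days. Every one of the 113 lay below the median signal of the probes tested, and 55 were well above background on all 8 arrays. Odorant, vomeronasal and trace amine receptor probes, a grouping chosen after the values were seen, made up 19 of the 113 (16.8%) and 994 (2.81%) of the probes tested, with a median fitted change of 0.63. The fitted shift of all probes ran from 0.63 in the dimmest of 5 equal groups by signal to 0.05 in the brightest. With quantile normalization limma called 0 probes higher and 0 lower. There 2848 had an unadjusted p under 0.05 (smallest adjusted p 0.263), against 6953 before, 6471 of them higher. The loss does not mean smaller changes throughout, as Ppp1r8, a lower call, had a fitted change of -2.31 before and -2.35 after. Of 30 alternatives, 19 gave no call. As a block, the replicate number left 0 and 0 by repetition number (7788 at an unadjusted p under 0.05) and 1 higher and 21 lower by source name number. Scan day as a block left 0 and 0 (9542), and slide as a random block 0 and 0 (3536). Leaving out NPRA+/+ replicate 1 gave 3901 and 187, and leaving out any other single array 0 and 0.

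**Figure D2:**
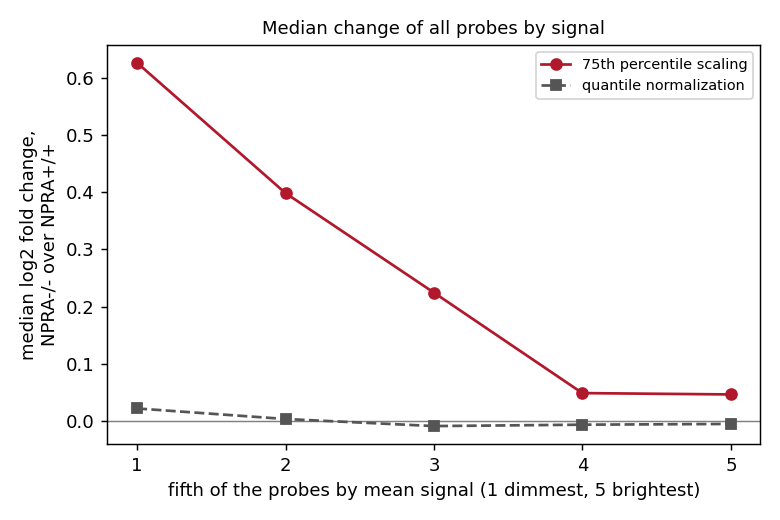
Median fitted log2 fold change (NPRA-/- over NPRA+/+, vertical axis) of the probes in 5 equal groups by mean signal (horizontal axis, dimmest first), after scaling to the 75th percentile and after quantile normalization. The first falls from 0.63 to 0.05, and the second lies between -0.01 and 0.02.

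Mesothelial markers were the only one of 35 gene lists past the threshold. The 7 measured members had a median change of 1.85, which is that of Krt19 (camera, adjusted p = 0.00305), and adjusted p = 0.356 with an estimated correlation. With normexp the median was 0.62. Without NPRA+/+ replicate 1 the adjusted p was 0.0772. All 7 members had positive fitted changes. Only Msln passed over all probes tested, and 4 passed adjusted over the list alone: Msln, Upk3b (uroplakin 3B) at 2.43 ± 0.54, Lrrn4 at 2.07 ± 0.52 and Krt19 (keratin 19) at 1.85 ± 0.39. Upk3b was well above background on 1, and Lrrn4 and Krt19 on 2, of the 5 NPRA+/+ arrays. Wt1, the brightest member, was at 0.02 ± 0.18, which turned negative with normexp, and Krt18 at 0.45 ± 0.36, with NPRA+/+ replicate 4 far below the other NPRA+/+ arrays. The fitted median was 2.06 over all arrays, 2.34 within scan day 1 (camera, adjusted p = 0.0382) and 1.45 after quantile normalization (adjusted p = 1.28e-04). With an estimated correlation these had an adjusted p of 0.789 and 0.735. With scan day as a block the list's change was 2.17 (camera, adjusted p = 0.0332, and adjusted p = 0.762 with an estimated correlation). That block takes the genotype difference from scan day 1, the only day with both genotypes. It is therefore the same estimate as within scan day 1, where the change relative to all probes was also 2.17.

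**Figure D3:**
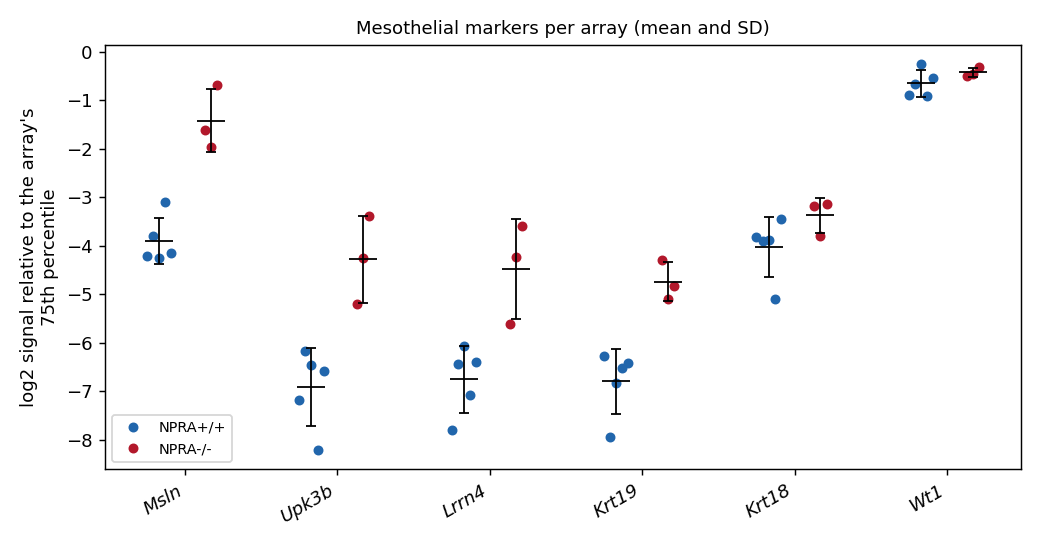
Log2 signal relative to the 75th percentile of 6 mesothelial markers on each array (points), with the mean and SD of the 3 NPRA-/- and 5 NPRA+/+ arrays (bars). Msln, Upk3b, Lrrn4 and Krt19 lie higher on all 3 NPRA-/- arrays, while Krt18 and Wt1 overlap; Upk3b was well above background on 1, and Lrrn4 and Krt19 on 2, of 5 NPRA+/+ arrays.

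None (0) of the 21 members of the natriuretic peptide and cyclic GMP list passed over all probes, nor 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. The list's median was -0.12 (camera, adjusted p = 0.416), while its fitted median (0.09) and mean (0.16) were positive and its relative median was positive after quantile normalization within scan day 1. Pde9a, a phosphodiesterase that degrades cyclic GMP, was at 0.15 ± 0.13, Npr3, the clearance receptor, at 0.32 ± 0.26, Pde3a at 0.41 ± 0.37 and Nppb, B-type natriuretic peptide, at 0.34 ± 0.34. Nppa, atrial natriuretic peptide, had levels of 5.53 ± 0.17 (SD, n = 3) and 5.41 ± 0.18 (SD, n = 5). None (0) of the 20 hypertrophy-associated genes passed either way (1 higher and 1 lower at an unadjusted p under 0.05; median -0.08, positive after quantile normalization and in the deposited table; adjusted p = 0.643). Its member Tnni1, slow skeletal troponin I, was at -1.77 ± 0.42 (adjusted p = 0.106), while Ankrd2 was at 0.25 ± 0.15, Actn1 at 0.38 ± 0.28 and Fhl1 at 0.28 ± 0.30. None (0) of the 36 genes of fatty acid uptake and oxidation passed either way (1 and 1 at an unadjusted p under 0.05; median -0.13; adjusted p = 0.183). Acot2, an acyl-CoA thioesterase, was at -0.70 ± 0.17, Pdk4, pyruvate dehydrogenase kinase 4, at -0.75 ± 0.24, Lpl, lipoprotein lipase, at 0.34 ± 0.23 and Echs1 at 0.07 ± 0.13, negative with normexp.

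**Figure D4:**
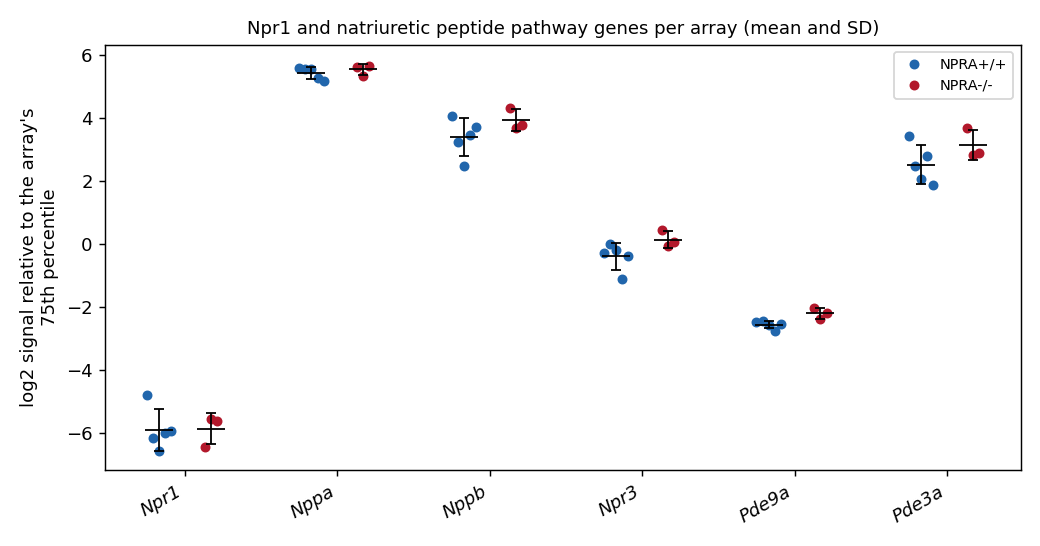
Log2 signal relative to the 75th percentile of Npr1 and 5 genes of natriuretic peptide signalling on each array (points), with the mean and SD of the 3 NPRA-/- and 5 NPRA+/+ arrays (bars). None of the 6 genes passed the test; relative to the median change of all probes Npr1 was at -0.18, and at 0.24 with normexp.

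With none of the alternatives applied no other function list passed, and none (0) of their members passed over all probes. At the preset correlation some lists passed lower under alternatives without a block, though none with an estimated correlation. With normexp these were fatty acid, branched-chain, immediate early and antioxidant genes. With array weights they were fatty acid, Dbp clock, immediate early, interferon and antioxidant genes. Immediate early genes also passed with the mean of a gene's probes and with probes above background on all arrays. Adjusted over the list alone, 1 immediate early gene, Nr4a3 at 0.71 ± 0.21, and 1 clock gene of the Bmal1 phase, Npas2 at 0.54 ± 0.22, passed. Across the alternatives the fitted change ranged from 0.30 to 1.11 for Nr4a3 and from -0.13 to 0.93 for Npas2. The immediate early list as a whole had a median of -0.28 (camera, adjusted p = 0.0658), antioxidant genes -0.22 (0.0658) and clock genes of the Dbp phase -0.33 (0.177). Calcium handling and ion channels were at -0.13 (0.224), the unfolded protein and integrated stress response at -0.18 (0.306), lipid synthesis at -0.03 (0.933) and glycolysis at -0.02 (0.950); the last 3 changed sign under at least 1 alternative other than scaling alone. The remaining medians changed sign under at least 1 of 4 other scalings. They were 0.18 for oxidative phosphorylation (0.177), -0.13 for branched-chain amino acid and ketone metabolism (0.311), -0.11 for the interferon response (0.629), -0.10 for m6A writers, erasers and readers (0.808) and 0.04 for the tricarboxylic acid cycle (0.823). Proliferation was at 0.04 (0.878), heat shock proteins at 0.01 (0.878), clock genes of the Bmal1 phase at 0.01 (0.933), inflammatory cytokines at 0.02 (0.933) and extracellular matrix genes at -0.04 (0.950). Among single members, Per3, a clock gene, was at 0.72 ± 0.25, Lss, lanosterol synthase, at -2.55 ± 0.62, Kcnj2, an inward rectifier potassium channel, at 0.27 ± 0.13 and Postn, periostin, at 0.31 ± 0.22, none past the threshold. With the replicate number as a block by source name number Lss passed (adjusted p = 0.0225), and so did the oxidative phosphorylation list (0.30, adjusted p = 1.03e-05, and adjusted p = 0.923 with an estimated correlation), whose median was 0.01 by repetition number and negative with normexp and within scan day 1. That list also passed with slide as a random block (0.25, adjusted p = 0.00219), where an estimated correlation was not run.

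Of the other cell type lists, none passed with camera and none of the alternatives applied. At the preset correlation neutrophil markers passed higher with normexp (camera, adjusted p = 0.0388). Thymocyte markers passed higher and erythroid markers lower with array weights (0.0312 and 0.0360). Thymocyte markers also passed higher with the mean of a gene's probes (0.0385). With an estimated correlation none of these passed. Neutrophil markers had a median of 0.24 (camera, adjusted p = 0.0658), and 0 of 12 members passed over all probes against 3 adjusted over the list alone. Its member S100a9 was at 0.83 ± 0.20 (adjusted p = 0.0693). With the replicate number as a block by source name number the neutrophil list passed (0.29, adjusted p = 0.0446, and adjusted p = 0.734 with an estimated correlation). Thymocyte markers were at 0.30 (0.124; 0 of 11, and 2 over the list alone) and lymphocyte markers at 0.17 (0.416; 0 of 14, and 3 over the list alone). Cardiomyocyte markers were at 0.33 (0.808), with Actc1, cardiac actin, at 0.54 ± 0.53 and Myh6, alpha myosin heavy chain, at 0.39 ± 0.45; a second probe of Myh6 had a fitted change of -0.09 ± 0.21. The cardiomyocyte list passed with the replicate number as a block by source name number (0.58, adjusted p = 0.0346, and adjusted p = 0.923 with an estimated correlation), while its median was 0.02 by repetition number. The cardiomyocyte median was negative within scan day 1 and, at -0.08, without NPRA-/- replicate 1. Skeletal muscle markers were at 0.11 (0.878), negative with the replicate number as a block and, at -0.05, without NPRA-/- replicate 1, and erythroid markers at -0.19 (0.484; 0 of 14, and 1 over the list alone). The other medians changed sign under at least 1 of 4 other scalings. These were -0.11 for smooth muscle and pericyte markers (0.878; 0 of 15, and 3 over the list alone), -0.13 for endothelial (0.643), 0.07 for fibroblast (0.643), 0.01 for nerve and Schwann cell (0.643) and -0.08 for atrial (0.878) markers. Adipocyte markers were at 0.04 (0.906), lung epithelial at -0.07 (0.940) and macrophage at -0.05 (0.950). A list whose count over the list alone is not given had 0 by both counts. Counts over the list alone carry the shift of all probes. Of the 35329 probes tested, 6471 were higher and 482 lower at an unadjusted p under 0.05 (limma). In the extracellular matrix, macrophage, proliferation and adipocyte lists camera ranked the members the other way from the median, and in the immediate early and antioxidant lists the fitted median and mean differed in sign. With fry, which tests a list without setting it against other genes, 5 lists moved up: mesothelial, neutrophil, lymphocyte, thymocyte and skeletal muscle markers.

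Within scan day 1, with 2 arrays of each genotype, 5494 probes were higher and 485 lower, and 0 and 0 (9809 at an unadjusted p under 0.05) after quantile normalization. Both NPRA-/- arrays of that day lay on 1 slide and both NPRA+/+ arrays on another. Over all arrays the correlation within slides was estimated at 0.87. Within scan day 1 genotype and slide were thus the same contrast, and the p-values measure only the spread within slides. Interferon response genes were lower there, with a fitted median of -0.20 (camera, adjusted p = 3.99e-04; adjusted p = 0.789 with an estimated correlation). Over all arrays their fitted median was 0.10. Their mean levels that day overlapped, at -0.49 and -0.35 in NPRA-/- against -0.46 and -0.05 in NPRA+/+ replicates 2 and 3, and replicate 3 lay far above the other NPRA+/+ arrays. Fatty acid genes (-0.05, adjusted p = 0.00408), clock genes of the Dbp phase (-0.22, 0.00328), erythroid markers (-0.13, 0.0137), antioxidant genes (-0.02, 0.0382) and branched-chain amino acid genes (-0.02, 0.0382) were also lower than other genes within that day, and thymocyte markers higher (0.64, 0.0382). With an estimated correlation each of these had an adjusted p of 0.789. With scan day as a block these lists passed too (adjusted p = 0.762 each with an estimated correlation). That block takes the genotype difference from scan day 1 alone, so it adds no separate evidence. After quantile normalization within the day only the interferon and mesothelial lists passed (adjusted p = 0.949 each with an estimated correlation). Clock genes of the Dbp phase were also lower with the replicate number as a block by repetition number (-0.30, adjusted p = 0.0305, and adjusted p = 0.951 with an estimated correlation).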

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

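The tests of the offset between arrays that quantile normalization removes, the background, the scan day and the levels at which the second list was measured were chosen after the result was seen; the counts of other splits, the second list of markers and the matched random lists were fixed before their results were.

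Among 137 genes, list means and measures of whole arrays in the NPRA+/+ arrays, 8 (5.84%) had 1 array far from the other 4, where chance gives about 5%. The values below are the gap to the nearest array as a share of the range, with a critical value of 0.71. NPRA+/+ replicate 1, which also stood apart on the first principal component, was far from the others for Mcam (0.721), C1qc (0.882), Cd4 (0.789), Hopx (0.753) and Satb1 (0.775), and lower than them in C1qc, Hopx and Satb1. NPRA+/+ replicate 4 was lowest for Krt18 (0.731) and for the mean of the lung epithelial markers (0.818). The mean of the interferon genes was -0.05 in NPRA+/+ replicate 3 and -0.43 in the next array (0.899).

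The higher probes lay at low signal. Of the 56 splits of the 8 arrays into 3 and 5, 1 (the real one) gave as many as 113 higher probes, and the highest of the others gave 14; the 8 splits that part all 3 numbered pairs, as the real one does, are too few for a share under 0.05 (113 against 0 for the highest other). An offset between arrays that depends on signal may account for it. Quantile normalization, which removes such an offset, left 0% of the calls. This loss cannot decide, since the calls lay just under the threshold and 19 of 30 alternatives gave none, among them fits at the same scaling. The median fitted change of the called probes went from 1.13 to 0.63, while that of all probes went from 0.21 to -0.002. Of the called probes 113 were still positive, 98 at an unadjusted p under 0.05. A higher background left after subtraction on the NPRA-/- arrays is argued against as the whole cause for the called probes, though not for the smaller shift of all dim probes. The subtracted signal of the negative control spots differed by 0.048 ± 0.24 (SE) percent of the 75th percentile. The higher probes, which were picked for their difference, differed by a median of 2.53 percent. The control spots' subtracted signal had a negative median on every array, whereas the processed signals compared here were all positive. How the processed signals were kept positive was not tested. The slides stay open, since no slide held both genotypes and they cannot be told apart from genotype.

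Mesothelial markers were the second pattern. The real split had the highest median of 56 (1 of 56), at 1.85 against 1.22 for the next. Among the 8 that part the pairs, too few for a share under 0.05, the highest other was 0.90. But the list was singled out as the top of 35. As many lists passed in 53 of the 56 splits, up to 16, against 1 in the real one. A smallest list p as small was found in 48 of 56, which leaves chance open for the lists as a whole. What makes lists pass in so many splits was not tested. The offset at dim probes is argued against as the whole cause, as the list's fitted median of 2.06 was at percentile 100 of 10000 random lists matched on signal (central 95% from 0.07 to 0.91), and so is scan day, with 2.34 within day 1 (adjusted p = 0.0382, and 0.789 with an estimated correlation). More mesothelial tissue, carried along at dissection, was tested on a second list of 20 markers, whose 10 dimmer members had a median of 0.091 ± 0.21 (SE) after quantile normalization, while all 20 had a camera p of 0.00127, and 0.0188 with an estimated correlation. This meets the bound written beforehand, but that bound was wrong: the 10 had a median level of -2.71 in NPRA+/+, against -6.78 for the 4 of the first list past the threshold over the list alone, which would hide a small share, so such tissue stays open beside slide, genotype and a change within mesothelial cells.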

How the results depend on the processing

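Scan day 1 alone, leaving out scan days 3 and 4, and the combinations of quantile normalization with scan day 1 or a block were chosen after the data were seen; the other alternatives were planned. The calls rest on few arrays and lie just under the threshold, and low signal over background limits them, since those higher were all below the median signal. No result reversed past the threshold. Of the single named genes, 2303 values kept their direction and side of the threshold, 328 lost a call, 94 gained one and 171 changed sign with no call on either side. For lists these were 799, 2, 64 and 149. Most of the 2303 belong to genes without a call. The named genes that were called passed in only 7 (Card6) to 9 (Msln and others) of 29 or 30 alternatives each. The cause was not tested unless given.

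Limma called 0 higher and 0 lower probes with quantile normalization, median scaling, normexp, the deposited series table, slide as a random block, scan day as a block, the replicate block by repetition number, averaged NPRA+/+ arrays, eBayes with trend and robust, and quantile normalization on scan day 1, with scan day or with the replicate block, with 2848 to 10514 probes at an unadjusted p under 0.05. The counts were 183 higher without a filter (10 lower) and 3 and 0 for probes above background on all 8 arrays, where fewer probes were tested. They were 1 and 21 with the replicate block by source name number, 8716 and 721 with array weights, which gave NPRA-/- replicate 1 a weight of 0.241 and NPRA+/+ replicate 1 a weight of 0.162, and 1363 and 208 with an unadjusted p and 2-fold. They were 92 and 6 with 1 probe per gene and 177 and 8 with the mean of a gene's probes. Leaving out 1 array gave 0 to 3901 higher and 0 to 187 lower, the highest without NPRA+/+ replicate 1 and 0 for the other 7 arrays. Among the named genes that passed only without NPRA+/+ replicate 1 on leaving out an array were Krt19, Upk3b, Lrrn4, Per3, S100a9 and Acot2. On scan day 1 alone, where each genotype lay on its own slide, the counts were 5494 and 485. They were 3954 and 180 without scan days 3 and 4.

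The fitted change of Npr1 was -0.60 with quantile normalization, -0.21 with median scaling, -0.59 in the deposited table, -0.20 with slide as a random block, -0.028 and -0.025 with the replicate block by repetition and by source name number, and -0.55 with quantile normalization and the replicate block. It ranged from -0.14 to 0.32 leaving out 1 array. It was negative in 11 of 29 alternatives, and relative to each alternative's median change of all probes in 20 of 29, and limma called it in 0 of them (smallest adjusted p 0.0517, on scan day 1 alone).

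Lists past the threshold at the preset correlation, higher and lower, were 1 and 0. They were 2 and 4 with normexp, 0 and 1 for probes above background on all arrays, where too few mesothelial markers were left for a test, 2 and 0 with slide as a random block and with averaged NPRA+/+ arrays, 2 and 6 with scan day as a block, with array weights and on scan day 1 alone, and 1 and 1 with the replicate block by repetition number. They were 4 and 0 with the replicate block by source name number (oxidative phosphorylation, cardiomyocyte, neutrophil and mesothelial markers), 2 and 1 with the mean of a gene's probes, 0 with an estimated correlation, 5 with fry, 3 and 6 without scan days 3 and 4, and 1 and 1 with quantile normalization on scan day 1 or with scan day as a block. Leaving out 1 array gave 1 to 3 higher and 0 to 6 lower. Mesothelial markers passed in 26 of 28 alternatives, with changes from 0.62 to 2.17 and adjusted p from 2.81e-05 to 0.356. The exceptions were the estimated correlation (1.85, adjusted p = 0.356) and leaving out NPRA+/+ replicate 1 (1.80, adjusted p = 0.0772); leaving out 1 array gave 1.56 to 1.96. Without NPRA+/+ replicate 1, oxidative phosphorylation passed in place of the mesothelial list (0.30, adjusted p = 0.0112, and adjusted p = 0.951 with an estimated correlation), a median that was negative with normexp. The oxidative phosphorylation list also passed without NPRA-/- replicate 2 (0.24, adjusted p = 0.0204) and without NPRA-/- replicate 3 (0.26, adjusted p = 0.00656), with an adjusted p of 0.965 and 0.897 with an estimated correlation. Leaving out NPRA-/- replicate 1 moved the most lists, with fatty acid, Dbp clock, immediate early, interferon, antioxidant and erythroid lists lower and neutrophil, thymocyte and mesothelial lists higher. Immediate early genes passed also without NPRA-/- replicate 3 or NPRA+/+ replicate 4, and antioxidant and neutrophil lists without NPRA+/+ replicate 4. Apart from slide as a random block, where it was not run, an estimated correlation left none (0) of the lists that camera called at the preset correlation under any alternative, the smallest adjusted p being 0.122 (antioxidant genes with normexp). The replicate block by repetition number changed no other list's call than that of the Dbp clock genes.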

Other observations

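The test of how the lower probes vary together was chosen after the result was seen, and its lower bound was set after its value was known.

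Of the 15 smooth muscle and pericyte markers, a list that did not pass, Myh11, smooth muscle myosin heavy chain, Lmod1, leiomodin 1, and Mylk, myosin light chain kinase, had fitted changes of 0.74, 0.67 and 0.58 and passed adjusted over the list alone, while Acta2, smooth muscle actin, and Smtn, smoothelin, had fitted changes of 0.26 ± 0.46 and -0.01 ± 0.13, 6 members were negative and the list's median was -0.11 relative to the shift. Across the alternatives the fitted change ranged from -0.24 to 0.995 for Acta2 and from -0.24 to 0.04 for Smtn. Myh11, Lmod1, Mylk, S100a8 and Mmp9 were named after their values were seen. Fry's mixed test, for changes in either direction, gave the list an adjusted p of 1.08e-04. Of the neutrophil markers, S100a8, S100a9 and Mmp9 passed adjusted over the list alone, with fitted changes of 1.06, 1.04 and 0.86, and 4 of 12 measured members had an unadjusted p under 0.05. Over all 35329 probes tested, 6953 had an unadjusted p under 0.05, 6471 of them higher. Such counts by themselves therefore do not set these 2 lists apart. Csf3r, the brightest member, was at -0.08 relative to the shift.

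The lower probes were few but bright. All 10 were well above background on all 8 arrays, 1 lay below the median signal, and their median fitted change was -2.07. When only probes well above background on all 8 arrays were tested, limma called 0 lower. The 10 calls thus depend on the dimmer probes tested beside them. Of the 56 splits, 1 gave as many as 10 lower probes and the highest other gave 2; the 8 splits that part all 3 numbered pairs are too few for a share under 0.05 (10 against 0 for the highest other). For Ppp1r8 only 1 of 2 probes differed, and 5 of the 10 carry no name here. A factor other than genotype that these probes share may move them together. Within genotype their median pairwise correlation was 0.26, at percentile 90.9 of 10000 matched random sets. This leaves open a factor that varies among samples of the same genotype. A difference in genetic background that is fixed between the genotypes would leave no such correlation, so the test cannot decide on it. A sequence difference under the probes was not tested.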
